A study of Homo sapiens with 6 samples.

How the data were processed

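RNA from AGS cells, a human gastric adenocarcinoma cell line, was sequenced 48 h after transfection with a control siRNA (siControl, 3 libraries) or with siRNA against USP22 (siUSP22, 3 libraries). Total RNA was harvested with Trizol and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The deposited tables give 1 value per gene name and library and name no unit. They were read as FPKM, because the deposited values, multiplied by the summed exon length of the gene in GENCODE release 29, were whole multiples of 1 step per library. All (100%) of the values above 0 came out whole within 0.02 reads, over the 56938 table entries that could be matched to 1 gene. Reads were mapped to hg38, per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and whether reads or fragments were counted are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart.

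Each table held 58735 entries with 57169 distinct names, and 58723 of the entries had a name found in GENCODE 29. A further 12 names read as calendar dates, as spreadsheet software makes them, and 1741 entries carried a name that occurs more than once. Both kinds were kept in the tests under their own entry but were given no coordinates and no recovered reads. Recovered totals were 17221455, 17729659 and 17710620 reads for siControl replicates 1, 2 and 3, and 17860173, 18235255 and 18386412 reads for siUSP22 replicates 1, 2 and 3. Between 97.9% and 99.5% of each total lay in genes that could be looked up. At these depths 3 reads in a gene of 1 kb correspond to an FPKM of 0.163 to 0.174. Such a floor covers counting error alone.

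The comparison was siUSP22 against siControl with the group as the only term. The test was fixed before the data were examined, for either counts or normalized values. As the values are FPKM, limma's moderated test (limma 3.58.1, R 4.3.3) with an intensity trend was applied to log2(FPKM + 1), over genes with an FPKM of at least 1 in at least 3 libraries. A gene with a mean FPKM under 1 in 1 group could pass only with libraries of the other group. Its direction is therefore partly set by the filter. Genes with a Benjamini-Hochberg false discovery rate (FDR) under 0.05 were called. Fold changes in log2 are on the log2(FPKM + 1) scale, which understates the change of genes with low values, while ratios given as fold are ratios of mean FPKM. All adjusted p-values of single genes are limma's. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

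A total of 25 gene lists were fixed before the data were examined. Each was tested with camera from limma, which compares a list with the other genes at a preset correlation of 0.01 between members, and again with a correlation estimated from the data. The fry test, which asks whether the members of a list move one way on balance, was run beside it. List p-values were adjusted over all 25 lists. A further 5 lists were added after the data were seen, and their p-values were adjusted over all 30 lists. The genes named are USP22, YAP1, WWTR1 and the YAP/TAZ target list. They also include the 10 largest rises and 10 largest falls among called genes with groups that did not overlap, an established name and a mean FPKM of at least 5 in the higher group. For the other lists, they are mostly members with the smallest p-values and called members. TEAD2, TEAD3, VIM, PTK2 and the members of added lists were named after their values were seen. Values of some single genes that this rule covers are not reported here.

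The test was checked on simulated data, with negative binomial reads drawn from the observed means at an assumed dispersion of 0.004 and 200 genes changed by known folds. Of genes changed 1.25-fold, 14% were recovered, against 60% at 1.5-fold, 80% at 2-fold and 96% at 4-fold, all with the right sign. In the same simulation of siUSP22 against siControl, with 12919 genes tested, 10 of 12728 unchanged genes were called. With so few changed genes the adjusted threshold is stricter than in the real comparison, so these shares do not carry over to it.

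Other filters, pseudocounts, scalings, thresholds, a replicate block and leaving out each library in turn were tried. After the data were seen, limma-voom on the recovered reads, totals without abundant genes and a restriction to protein-coding genes were added. Tests planned for deposited counts were not run. For the closing observations, the principal protein of each gene in GENCODE 29 was scored by Kyte-Doolittle hydropathy. A protein was classed as having an N-terminal hydrophobic stretch where a window of 10 residues starting within the first 25 had a mean of at least 2.0 (1.5 and 2.5 were also tried). Otherwise it was classed as having an internal stretch where a window of 19 residues after residue 40 had a mean of at least 1.6.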

Results

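Gene expression was measured by RNA sequencing in AGS human gastric cancer cells 48 h after siRNA transfection, with 3 siControl and 3 siUSP22 libraries. USP22 is a deubiquitinating enzyme of the SAGA transcriptional coactivator complex, and the series concerns its part in the Hippo/YAP pathway. The design text names 2 siRNA sequences against USP22. It does not say which sequence went into which library, so the siUSP22 libraries were treated as 1 group. Recovered depth was 17221455 to 18386412 reads per library. Pearson correlations of log2(FPKM + 1) across tested genes were 0.988 to 0.992 between libraries of the same group and 0.903 to 0.909 between groups. Replicates differed by more than sampling noise (chi-square per degree of freedom 2.32 to 6.84), so none was a duplicate of another. The first principal component held 87.9% of the variance and separated the groups, and the second held 3.89%.

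USP22 itself was examined first, as a check of the labels, and was lower in every siUSP22 library than in every siControl library. The gene (ENSG00000124422.11, chromosome 17, 20999593 to 21043760, minus strand, hg38) had 35.0 ± 0.278 FPKM in siControl and 2.63 ± 0.171 FPKM in siUSP22 cells (mean ± SD, n = 3 each). This was a 13.3-fold fall, with a log2 fold change of -3.31 (SE 0.0457, limma adjusted p = 1.04e-08). The recovered reads were 4127, 4187 and 4236 in siControl replicates 1 to 3 and 344, 317 and 315 in siUSP22 replicates 1 to 3.

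The siUSP22 cells differed from siControl cells in most expressed genes. Heat-shock genes, metallothioneins and stress transcription factors were among the 10 largest rises, and matrix and cell-surface genes were among the 10 largest falls. Of 13132 genes tested, 5335 rose and 4220 fell at an FDR under 0.05. Large changes were mostly falls: 1104 genes fell and 327 rose by at least 2-fold on the log2(FPKM + 1) scale, and 219 fell and 24 rose by at least 4-fold. The values of the groups did not overlap in 9968 genes (75.9%), against 10% given by chance for 3 against 3. The higher share of called genes was 55.8%, and between 49.5% and 61.3% under the other scalings tried.

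HSPA6, an inducible HSP70 chaperone, rose 243-fold from 0.664 ± 0.0638 to 161 ± 9.05 FPKM (mean ± SD, n = 3 each). The HSP70 genes HSPA1A and HSPA1B rose 22.6-fold and 21.9-fold, and their co-chaperone DNAJB1 rose 8.31-fold. The metallothioneins MT1M, MT1E and MT1F, which bind zinc and copper, rose 22-fold, 11-fold and 8.93-fold. The stress-response genes DDIT4, DDIT3 and ATF3 rose 14.9-fold, 12-fold and 11.5-fold. HSPA1A and HSPA1B are near-identical copies, and HSPA6 and the MT1 genes have close relatives, so the values of single members are uncertain. Fibronectin (FN1) fell 34.4-fold, from 85.8 ± 5.61 to 2.49 ± 0.0235 FPKM. The matrix genes TNC and COL5A1 fell 38.2-fold and 17.7-fold, MAMDC2 fell 29.4-fold, and the surface proteins DAG1 (dystroglycan) and PODXL (podocalyxin) fell 18.8-fold and 13.5-fold. The other large falls were the mitochondrial tRNA genes MT-TH, MT-TR, MT-TG and MT-TK. They are short and lie beside mitochondrial mRNAs, so their values are uncertain.

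**Figure D1:**
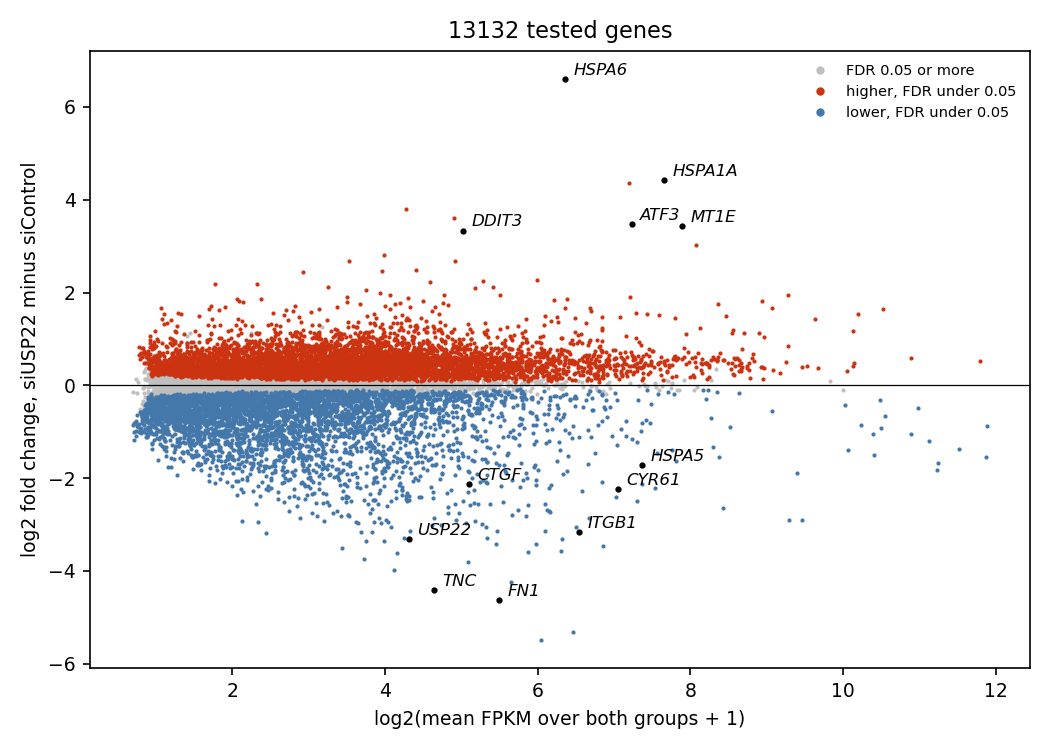
Log2 fold change (siUSP22 minus siControl, vertical axis) against log2 of the mean FPKM over both groups plus 1 (horizontal axis), with 1 point for each of 13132 genes tested. Red and blue points are genes higher and lower at an FDR under 0.05, and grey points are the others. The deep falls outnumber the large rises (219 against 24 at 4-fold or more on the log2(FPKM + 1) scale).

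The expression of YAP/TAZ target genes addressed the pathway named by the series. Most targets were lower in siUSP22 cells. CYR61 (chromosome 1, 85580761 to 85583962, plus strand) fell 4.77-fold, from 218 ± 1.10 to 45.6 ± 0.770 FPKM (mean ± SD, n = 3 each; log2 fold change -2.23, SE 0.0294, limma adjusted p = 8.96e-09). CTGF (chromosome 6, 131948176 to 131951373, minus strand) fell 4.65-fold, from 54.7 ± 1.86 to 11.8 ± 0.655 FPKM (log2 fold change -2.13, SE 0.0488, limma adjusted p = 6.35e-08). Both encode secreted matrix-associated proteins and are widely used readouts of YAP activity.

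Of 21 YAP/TAZ targets tested, 18 fell and 2 rose, and the counts adjusted over the list alone were also 18 and 2. CRIM1 fell 8.57-fold, IGFBP3 6.31-fold, TGFB2 6.27-fold and the receptor tyrosine kinase AXL 4.08-fold. GADD45A, a stress-induced growth arrest gene, rose 3.08-fold and ANKRD1 rose 1.24-fold, while FOXF2 was not called (1.03 and 1.20 FPKM). The median log2 fold change was -0.999, and camera placed the list below the other genes (adjusted p = 8.26e-07; adjusted p = 0.0538 with an estimated correlation). Mitochondrial mRNAs fell in the same libraries (median -1.39).

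The coactivators themselves fell by less than CYR61 and CTGF. YAP1 fell 1.35-fold (38.3 ± 0.870 to 28.5 ± 0.427 FPKM) and WWTR1, which encodes TAZ, fell 1.53-fold (12.6 ± 1.40 to 8.23 ± 0.285 FPKM). Of 29 Hippo pathway genes, 18 fell and 4 rose, the same counts as adjusted over the list alone. The atypical cadherin FAT1 fell 16.9-fold and the kinase gene LATS2 fell 2.27-fold. Of the DNA-binding partners, TEAD4 and TEAD1 fell 2.85-fold and 1.52-fold, while TEAD2 and TEAD3 were not called (-0.11 and 0.17 on the log2 scale). RASSF1 and the kinase gene STK3 rose 2.68-fold and 1.57-fold. The list had a median of -0.39 and was called lower (camera adjusted p = 0.00342; adjusted p = 0.0961 with an estimated correlation).

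**Figure D2:**
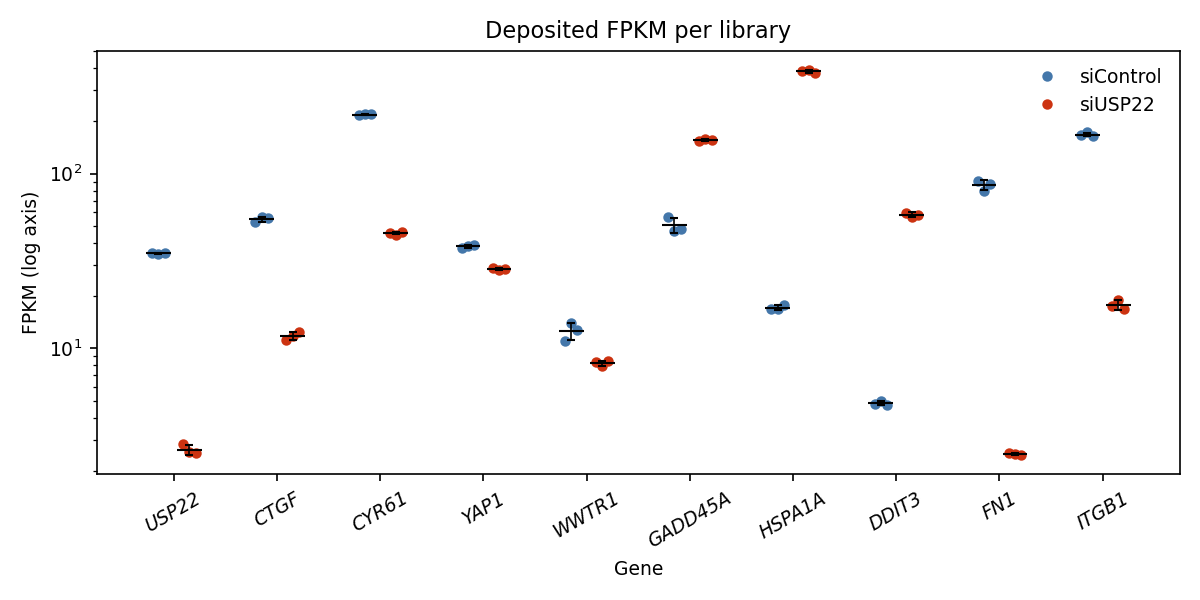
Deposited FPKM on a log axis for 10 genes (horizontal axis), with 1 dot per library, blue for siControl and red for siUSP22, and black bars for the mean ± SD of 3 libraries. The libraries of the groups do not overlap for any gene shown: CYR61, for example, had means of 218 and 45.6 FPKM.

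Among 24 tested SAGA complex genes, which include USP22, 13 rose and 4 fell, also when adjusted over the list alone. Besides USP22, the scaffold gene TRRAP fell 2.44-fold, the acetyltransferase gene KAT2A 1.43-fold and SF3B3 by 0.20 on the log2 scale. SGF29 rose from 5.25 to 10.1 FPKM. The list was not called (median 0.20, camera Up, adjusted p = 0.188), though camera called it Up without the filter on low values (adjusted p = 0.00920). That run compared it with a wider set of 35321 genes, of which 27.7% were called. Fry gave the opposite direction (Down, adjusted p = 0.0314). USP22, the siRNA target, had the largest change in the list, and the list was not rerun without it.

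Of 23 focal adhesion and matrix receptor genes, 22 fell and none rose, also when adjusted over the list alone, and the kinase gene PTK2 was not called (20.7 and 20.5 FPKM). ITGA2 fell 25.1-fold, ITGA6 12.3-fold, ITGB1 9.43-fold (167 ± 4.10 to 17.7 ± 1.19 FPKM) and ITGA3 8.80-fold. The median log2 fold change was -1.31, and -2.48 when limma-voom was run on recovered reads, a choice made after the data were seen (camera adjusted p = 1.33e-10; adjusted p = 0.0961 with an estimated correlation). Of 11 mesenchymal genes, 7 fell and 2 rose: SPARC fell 4.44-fold, whereas vimentin (VIM) was not called (173 and 170 FPKM). Their median was -2.08 (camera adjusted p = 0.0109; adjusted p = 0.104 with an estimated correlation). Of 13 TGF-beta targets, 10 fell and none rose, with TGFBI 7.39-fold and ID1 3.65-fold lower (median -1.11, camera adjusted p = 5.96e-05; adjusted p = 0.0961 with an estimated correlation). For both lists the counts adjusted over the list alone were the same.

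Few marker genes of other cell types passed the expression filter: 3 of 10 for fibroblasts, 1 of 8 for endothelial cells and 3 of 15 for immune cells. Those that passed fell in the same libraries. The 3 tested fibroblast markers, LUM, FAP and MMP2 (the last also in the mesenchymal list), all fell (median -2.08, camera adjusted p = 0.0182; adjusted p = 0.226 with an estimated correlation). The 3 tested immune markers, HLA-DRA, CD74 and CD14, all fell (median -1.01, camera adjusted p = 0.0279; adjusted p = 0.227 with an estimated correlation). The immune call was also lost without a filter (adjusted p = 0.119), with a minimum FPKM of 5 (adjusted p = 0.0715) and with limma-voom after median-ratio scaling (adjusted p = 0.0532). The only tested endothelial marker, TEK, fell by 1.59 on the log2 scale, and its list was not called (adjusted p = 0.146). These counts were the same when adjusted over the list alone.

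Genes of the ATF4 stress response rose. Of 19 tested, 16 rose and 3 fell, also when adjusted over the list alone: SESN2 rose 8.98-fold, CHAC1 8.72-fold, TRIB3 4.54-fold and ATF4 itself 2.97-fold, while the amino acid transporter gene SLC7A5 fell 6.11-fold. The median was 1.35 (camera adjusted p = 0.000137; adjusted p = 0.0961 with an estimated correlation). Genes of endoplasmic reticulum protein folding split. Of 17 tested, 11 fell and 5 rose (11 and 6 adjusted over the list alone). CANX fell 5.77-fold, HSP90B1 4.32-fold, HSPA5 3.34-fold and CALR 3.13-fold, all chaperones of that compartment. HERPUD1 rose 6.44-fold, XBP1, a transcription factor of the unfolded protein response, 4.53-fold, DNAJB9 2.61-fold and MANF 2.57-fold. The list was called lower (median -1.31, camera adjusted p = 0.0185; adjusted p = 0.112 with an estimated correlation).

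Cholesterol genes also went both ways. Of 21 tested, 11 fell and 7 rose, also when adjusted over the list alone. SQLE, an enzyme of cholesterol synthesis, fell 5.05-fold, while IDI1 and FDFT1 rose 1.93-fold and 1.68-fold. The list was not called (median -0.16, adjusted p = 0.146). Of 20 hypoxia and glycolysis genes, 7 rose and 7 fell, with the glucose transporter gene SLC2A1 falling from 58.4 to 11.3 FPKM and VEGFA rising from 3.95 to 6.57 FPKM. This list was not called either (median -0.03, adjusted p = 0.694), and its median depended on scaling, from -0.13 by limma-voom with median-ratio scaling, a choice made after the data were seen, to 0.038 with median centring. The list-alone counts were again 7 and 7.

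Replication genes rose modestly. Of 26 S-phase genes, 17 rose and 2 fell, also when adjusted over the list alone, with CDC6 2.19-fold, DTL 2.20-fold and PCNA 1.51-fold higher (median 0.31, camera adjusted p = 0.0109; adjusted p = 0.0961 with an estimated correlation). The call of this list was lost when genes under an FPKM of 5 were left out (adjusted p = 0.0731). Of 25 G2/M genes, 12 rose and 9 fell (13 and 9 adjusted over the list alone). The proliferation marker MKI67 fell 2.75-fold, while AURKB and TTK rose from 28.1 to 45.4 and from 30.7 to 50.8 FPKM. CCNB1 and TPX2, counted as higher, turned lower under quantile normalization (-0.050 and -0.13). The G2/M list was not called (median 0.11, camera Up, adjusted p = 0.810; fry Down, adjusted p = 0.378), and its median changed sign under quantile normalization (-0.082).

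Of 22 p53 targets, 14 rose and 5 fell. CDKN1A, the cell cycle inhibitor p21, rose 1.95-fold, and the death receptor gene TNFRSF10B fell from 23.3 to 8.45 FPKM. Of 19 apoptosis regulators, 11 rose and 4 fell, and PMAIP1, a proapoptotic BH3-only gene, rose 3.76-fold. MCL1, one of the 11, turned lower under quantile normalization (-0.10). Neither list was called by camera (median 0.32, adjusted p = 0.146, and median 0.15, adjusted p = 0.178). Both were called Up by camera without the filter on low values (adjusted p = 0.00451 and 0.0184) and by fry (adjusted p = 2.81e-05 and 0.000167). Neither result sets these lists apart. Fry called 24 of the 25 lists, where 72.8% of all tested genes were called. Without the filter, the lists were compared with a wider set of 35321 genes, of which 27.7% were called. All of these counts were the same when adjusted over the list alone.

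Ribosome genes rose together. All 28 tested ribosomal protein genes rose, also when adjusted over the list alone, by a median of 0.56 (camera adjusted p = 3.92e-08; adjusted p = 0.0538 with an estimated correlation). Under quantile normalization this median was 0.25, and RPS2 turned lower (-0.084). Of 20 MYC and ribosome biogenesis genes, 17 rose and 1 fell, with the nucleolar genes NOP58 and NOP56 rising from 69.0 to 133 and from 50.3 to 82.1 FPKM. NCL, also counted as higher, turned lower under quantile normalization (-0.11). Their median was 0.37, and 0.24 under quantile normalization (camera adjusted p = 0.000707; adjusted p = 0.0961 with an estimated correlation), and the counts adjusted over the list alone were the same. MYC itself rose 2.14-fold.

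Of 21 interferon-stimulated genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone). IFI27 rose 3.40-fold, ISG15 2.28-fold and MX1 2.01-fold, and OAS3 fell from 16.3 to 13.3 FPKM. The median was 0.35 (camera adjusted p = 0.00390; adjusted p = 0.0961 with an estimated correlation). Of 20 NF-kB and inflammatory genes, 13 fell and 5 rose, also when adjusted over the list alone. ICAM1 fell 6.82-fold and the chemokine gene CXCL1 5.49-fold, while the cytokine gene IL1B rose 2.75-fold (median -0.51, camera adjusted p = 0.0279; adjusted p = 0.327 with an estimated correlation).

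Of 9 Wnt targets, 6 fell and 3 rose, with CCND1 1.93-fold lower, and the list was not called (median -0.46, adjusted p = 0.146). Of 14 epithelial genes, 6 fell and 4 rose. EPCAM fell 1.94-fold and the desmosome gene DSP 1.77-fold, while KRT18 rose 1.43-fold. KRT8 and KRT19, also among the 4 that rose, turned lower under quantile normalization (-0.069 and -0.24). The epithelial list was not called (median -0.11, adjusted p = 0.482). Of the gastric lineage genes, 4 of 25 passed the expression filter: MUC1 and GATA4 fell and CDX2 rose (1 higher and 2 lower; 2 and 2 adjusted over the list alone; median -0.09, adjusted p = 0.694). For the Wnt and epithelial lists, adjustment over the list alone gave the same counts.

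Mitochondrial transcripts took a smaller share of the reads in siUSP22 cells. Mitochondrial genes held 3.61%, 4.18% and 3.81% of recovered reads in siControl replicates 1 to 3 and 1.97%, 1.89% and 2.16% in siUSP22 replicates 1 to 3. All 13 mitochondrial mRNAs fell, also when adjusted over the list alone. MT-ND5, a subunit of respiratory complex I, fell 7.48-fold, from 1239 to 166 FPKM, and MT-CO1, a subunit of cytochrome c oxidase, fell 2.93-fold. The list median was -1.39, and -0.86 under quantile normalization (camera adjusted p = 2.68e-06; adjusted p = 0.227 with an estimated correlation).

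Of the 25 lists, 15 were called by camera with the preset correlation, 5 higher and 10 lower. With an estimated correlation 0 were called when adjusted over these 25 lists. Fry called 24, all but the G2/M list, where 72.8% of all tested genes were called. Only the YAP/TAZ list was later compared with genes of the same hydrophobic stretch classes. For the other lists, how far their changes exceed the general changes of those classes was not tested. The ATF4 median of 1.35 (16 of 19 higher, 3 lower) lay above the upper quartile of genes with neither stretch (0.48).

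**Figure D3:**
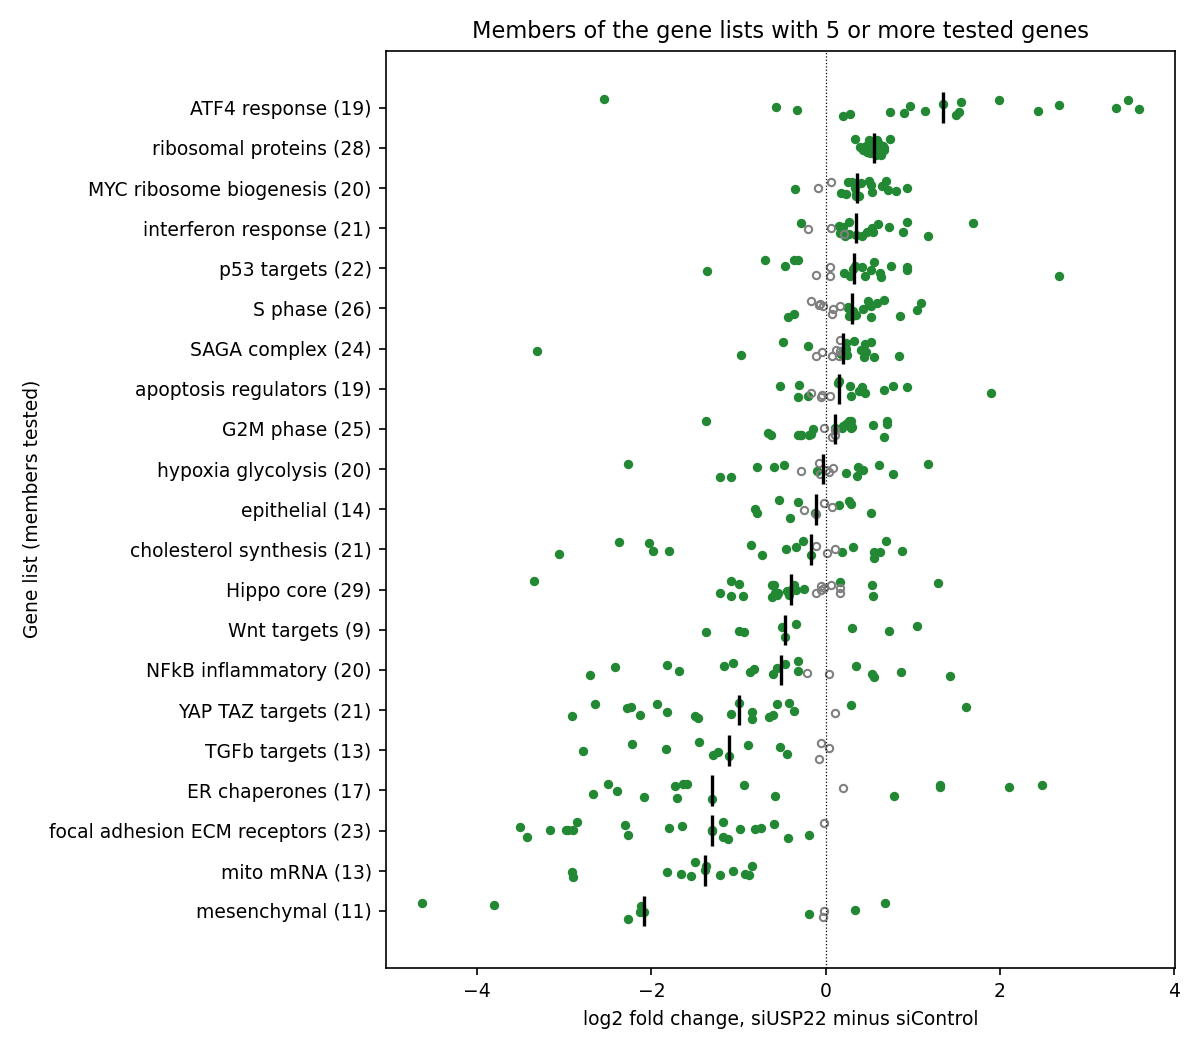
Log2 fold change (siUSP22 minus siControl, horizontal axis) of each tested member of the gene lists (vertical axis, number tested in brackets), for lists with 5 or more tested genes. Green dots are members with an FDR under 0.05, open grey dots are the others, and black bars are list medians, from -2.08 for mesenchymal genes to 1.35 for the ATF4 response; the median of the G2/M list changes sign under quantile normalization (-0.082).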

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

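The runs on recovered reads, without abundant genes, on protein-coding genes and on YAP/TAZ targets with neither hydrophobic stretch were chosen after the data were seen. The count of changed genes (9555) kept within 1.5 times of its value under all settings except 2. A minimum FPKM of 5 gave 6355 genes, 2397 of them lower, because 7546 genes were tested, and the original test calls 6284 of those. A log2 fold change of at least 1 gave 1431 genes, 327 higher and 1104 lower. Leaving out single libraries gave 8270 to 8881 genes, 4808 to 5207 higher and 3351 to 4017 lower, a USP22 log2 fold change of -3.35 to -3.29, 15 to 15 called lists and an adjusted p of 3.21e-07 to 1.79e-06 for the YAP/TAZ list. Over all its alternatives that adjusted p ran from 1.73e-11 without a filter to 0.0538 with an estimated correlation, and was 0.146 for its members with neither stretch; the cause was not tested. An estimated correlation called 0 gene lists and fry 24. For the YAP/TAZ and ribosomal protein lists the estimates (0.00011 and -0.0081) lay below the preset 0.01. A larger correlation between members therefore did not end those calls. For other lists, such as the focal adhesion genes (0.13), the estimate lay above it. For the YAP/TAZ list, camera's unadjusted p rose from 9.91e-08 to 0.00430 although its estimate was the smaller correlation. For the interferon list, with an estimate of 0.011 near the preset, it rose from 0.00140 to 0.0342. For these lists the run was thus stricter mainly for a reason other than correlation between members. A call lost in that run does not by itself show correlated members. That reason was not tested further. Fry gave SAGA genes, with the siRNA target USP22 among them, as Down (0.0314). Quantile normalization reversed CCNB1 (-0.050), TPX2 (-0.13), MCL1 (-0.10), KRT8 (-0.069), KRT19 (-0.24), NCL (-0.11) and RPS2 (-0.084); the cause was not tested. Among uncalled lists, scaling also moved medians by over 1.5 times: p53 targets to 0.50, apoptosis regulators to 0.063, epithelial genes from -0.26 to -0.049, cholesterol genes from -0.26 to -0.098, hypoxia and glycolysis genes from -0.13 to 0.038, gastric genes from -0.26 to -0.027 and TEK to -2.41. The replicate numbers did not pair the samples (same-number correlations of deviations -0.04, -0.12 and -0.01). A replicate block called 9094 genes and ended no list call. Of 6594 other comparisons of single genes, 6429 were the same, 152 lost and 6 gained the call. Of 479 for single lists, 449 were the same, 18 lost and 11 gained it. Alternatives planned for counts (other size factors, other count tests, thinning) were not run, as the values are FPKM. Genes under a mean FPKM of 5 had a median of 171 reads per library and 61.4% were called, against 1167 reads and 82.4% of the others; how far depth sets this was not tested.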

Other observations

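The added gene lists, the stretch classes, the tests on mitochondrial rRNAs and on labels of a day and the bound on shifts of the totals were chosen only after the result was seen. Heat-shock genes rose as a group: of 23 tested, 21 rose, SERPINH1, a chaperone of the endoplasmic reticulum, fell (-0.68), and HSP90AB1 was not called (-0.10). The median log2 fold change was 1.64 (camera p adjusted over 30 lists = 6.91e-09; adjusted p = 0.0436 with an estimated correlation). Values adjusted over 30 lists cannot be set against those adjusted over 25. Before adjustment, camera's p with an estimated correlation was 0.00436 for heat-shock genes. It was lower for the YAP/TAZ list (0.00430) and the ribosomal protein list (0.00261). BAG3 rose by 2.24, HSPB1 by 1.75, DNAJA1 by 1.67 and HSP90AA1 by 1.53 on the log2 scale. All 5 tested metallothioneins rose, with a median of 2.8 (camera adjusted p = 0.00245; adjusted p = 0.132 with an estimated correlation). Of 29 proteasome subunit genes, 25 rose and none fell, with a median of 0.44 (camera adjusted p = 1.99e-05; adjusted p = 0.0482 with an estimated correlation). All 11 tested histone H2B genes rose, with a median of 1.64 (camera adjusted p = 0.000166; adjusted p = 0.0741 with an estimated correlation). Of these, HIST1H2BE, HIST1H2BF, HIST1H2BH, HIST1H2BN and HIST1H2BO had siControl means of 0.287 to 0.948 FPKM. They passed the expression filter only with siUSP22 libraries, so their direction was partly set by the filter and the list's p-values overstate the rise. HIST1H2BK, the most abundant, went from 118 to 326 FPKM, and HIST1H2BJ from 7.49 to 38.5 FPKM. H2B genes are similar in sequence, so the values of single members are uncertain. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 rose by 1.43 and 0.52 on the log2 scale, while all 13 mitochondrial mRNAs fell. As a list of 2, the rRNAs were not called (camera adjusted p = 0.154).

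Transcripts whose protein starts with a hydrophobic stretch, as signal peptides do, fell as a class. Of 1829 tested, 69.8% fell and 14.6% rose (median -0.64; camera p = 2.32e-25, and p = 7.25e-06 with an estimated correlation), against 21.2% and 54.5% of 7272 genes with neither kind of stretch (median 0.21). The size depended on the hydropathy minimum: with 1.5 in place of 2.0, 53% fell and 28.6% rose (median -0.25), and with 2.5, 78.7% fell (median -0.84). It also depended on protein length. Stretch proteins of up to 200 residues (243 genes) had a median of -0.017, with 37.4% lower, and those of over 800 residues had a median of -1.10, with 84.4% lower. Stretch minus neither, the difference of medians was -0.37 up to 200 residues, -0.76 above 200 and up to 400, -1.14 above 400 and up to 800, and -1.02 above 800. On the log2(FPKM + 1) scale, 204 classed genes fell by at least 4-fold. Genes with the stretch made up 83.8% of them, against 16.6% of all tested genes with a class, and genes with an internal stretch 11.3%. The fall was not confined to N-terminal stretches. Of 1948 genes with an internal stretch, 46.5% fell and 30.1% rose (median -0.12; camera Down, p = 0.000336, and p = 0.000195 with an estimated correlation).

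The split of the 6 libraries by group gave 9555 changed genes, and the highest of the other splits gave 1. As many genes came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

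For the fall of the stretch class, gene length, GC content and expression do not account for the whole difference: computed across genes that are not independent, it was -0.91 both before and after adjustment (95% interval -0.94 to -0.88), though its size varied with protein length. A general loss of RNA bound to organelles, mitochondria included, predicted a fall of the mitochondrial rRNAs, the lower of which rose by 0.52. That test was chosen after the rise was seen, and how the libraries treated rRNA is not stated here, so it cannot decide. Loss of RNA at the endoplasmic reticulum alone from the libraries predicted that fewer than 5% of the class would rise, and 14.6% did. The bound set against it, over 20% rising by at least 0.5 on the log2 scale, was not met either (5.58%), so it stays open. Decay of such RNA in stressed cells, or another effect of USP22 loss, may be a biological source and stays untested.

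Since CYR61, CTGF and 7 other YAP/TAZ targets have an N-terminal stretch, the fall of that list may partly follow the fall of the class. The list median of -0.999 lay at percentile 0.010 of 10000 random lists with the same mix of classes and expression, the lowest they can give, where the random median was -0.08. The 8 members with neither stretch had a median of -0.58, also at percentile 0.010, although camera did not call them (adjusted p = 0.146). They hold every member of the list that did not fall: GADD45A (1.61), ANKRD1 (0.29) and the uncalled FOXF2 (0.11). A median takes no account of how far these rose. The 9 members with an N-terminal stretch (median -2.13) lay at percentile 0.130 of lists of their class. The class as matched leaves part of the fall open. The random lists were not matched on protein length, though, and medians fell with length in both classes (-1.10 and -0.08 above 800 residues). They cannot show whether class and length together account for the fall. Whether lower YAP activity or another effect of the siRNA accounts for it was not tested.

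For the rise of heat-shock and stress genes, mitochondrial genes and the 10 most abundant genes do not account for it: they could shift the totals by at most 0.065 on the log2 scale, against a heat-shock median of 1.64, and HSPA1A rose by 4.43 with them left out. An innate response to the transfected siRNA predicted a rise of the interferon list, which was called higher (median 0.35). That rise cannot decide it, as genes with neither stretch had a median of 0.21 and ribosomal protein genes rose by 0.56. Both groups were also transfected. The interferon call was lost with an estimated correlation, but that run called 0 of the 25 lists. Its loss is therefore not particular to interferon genes and does not weigh on this question. A difference in day or handling between the groups cannot be told apart from the knockdown, since 0 libraries have a label for day or batch. Off-target effects could not be separated either, because the labels do not tie a siRNA sequence to a library. Stress after loss of USP22 stays an untested hypothesis.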
